A study of Mus musculus with 4 samples.

How the data were processed

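The series holds 4 one-colour Agilent arrays of mouse erythrocyte/megakaryocyte progenitors on a C57BL/6 background, 1 for each combination of source (E14.5 fetal liver or adult bone marrow) and genotype (wild type or Ezh2-null). Groups and genotypes were taken from the sample titles. Per the labels' protocols, total RNA was extracted with Trizol, and 250 ng was mixed with Agilent one-colour spike-in RNA, amplified and labelled with Cy3. The labels do not say how the progenitors were isolated, how many animals of which sex gave each sample or which part of Ezh2 was deleted. All arrays lay on 1 slide and were scanned on 1 date, so slide and scan cannot separate the groups.

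The deposited intensity values are Agilent Feature Extraction 10.7.3.1 output (protocol GE1_107_Sep09), per the file headers. Per the file headers, the processed intensity of each spot had been background-subtracted with a spatial detrend surface, detrended multiplicatively within the array and replaced by a surrogate where it was low, with no step between arrays. The mean spot intensity and the median local background intensity, used for 1 alternative, were as scanned, per the file headers. The other deposited columns used were flags of 0 or 1 that Feature Extraction set per spot for signal well above background, saturation and outliers. The authors' series table held the same processed intensities rounded to 3 significant digits. Its column medians were 7.05, 10.8, 10.3 and 8.63 in the order fetal liver wild type, fetal liver null, bone marrow wild type, bone marrow null, on a linear scale without centring, and no value differed from the scanner file by more than 0.496%.

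Control spots were left out, as were spots with an outlier flag, which numbered 101, 97, 95 and 135 in that order; 11 probes had no unflagged spot on some array. No spot was saturated. Spots of 1 probe were averaged, which left 39418 probes from 43020 spots. Log2 processed intensities were scaled so that the 75th percentile over the 12874 probes well above background on all 4 arrays was equal. The plan fixed before the data were examined named the 75th percentile of the array. Under 50% of the probes were well above background on every array, and the percentile was therefore taken over detected probes; the version over all probes was added as an alternative after seeing the data. The lowest scaled signal among probes well above background was the floor of each array (19.3, 13.0, 11.1 and 9.99 in the same order). A gene not well above background on 1 array of a pair was given as a bound, the bright signal against the higher of that floor and the dim probe's own signal, and written as at least N-fold. A bound that would put the dim side above the bright one was entered as no difference. Genes dim on both arrays of a pair were left out of that pair. For 399 probes printed 10 times, the median log2 SD between spots of 1 array was 0.152, 0.104, 0.0752 and 0.101 in that order, over the copies well above background. That figure covers the error within an array only, and the number of arrays limits the precision.

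Gene names came from the files and were updated through a RefSeq gene table of assembly GRCm38.p6, used for names only. It named 26048 probes by accession, 3193 by symbol and 929 by an older name, and 9248 probes kept the name in the files. This gave 31703 genes or other names, of which 17663 were well above background on at least 1 array and 11171 on all 4. The probe with the highest mean log2 signal stood for a gene with several probes (6398 genes). Where a called gene had another probe measured on both arrays, that probe went the same way for 75.6% of 495 genes in fetal liver by genotype, 73.0% of 126 in bone marrow by genotype, 83.5% of 612 between the sources in wild type and 80.8% of 593 in null. It was also at least 2-fold apart that way for only 43.0%, 24.6%, 53.1% and 49.6% in that order. Coordinates are those of the files, on build mm9.

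With 1 array per group no test between 2 arrays was possible, and a gene was called when its difference was at least 2-fold (1 on the log2 scale). For the 4 pairwise comparisons the calls were split by direction and by bound. Calls shared by both sources were set beside the number independent lists would share per direction, the product of the list lengths over the genes compared. The difference of differences was called at 4-fold. One fit had a residual: limma 3.58.1 (R 4.3.3) with source and genotype as additive terms over the 4 arrays, 2 per genotype and 2 per source, two-sided, with Benjamini-Hochberg adjustment over 16249 genes and a threshold of 0.05. In the main setting, signals under the highest array floor (19.3) were raised to it before the fit. The labels do not say whether the arrays of 1 source shared animals, and the 1 residual degree of freedom of the fit holds the disagreement of the genotype differences between the sources. On simulated data it recovered 0.2%, 0.8%, 72.8% and 97.6% of genes changed by 1, 2, 4 and 6 log2 units, and 9.12% of its calls were false.

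The plan fixed 21 gene lists with 526 entries, of which 521 matched a name: PRC2 and PRC1 components, developmental transcription factors, Hox genes, cell cycle inhibitors, proliferation, erythroid, globin and globin switching, megakaryocyte, stem and multipotent progenitor, granulocyte and macrophage, mast cell with basophil and eosinophil, lymphoid, hepatocyte, endothelial and stromal, fetal-type progenitor, imprinted, sex-linked, immediate-early and stress, interferon-stimulated, p53 and apoptosis, and reference genes. Each list is given by its measured members, the number at least 2-fold higher and lower, and its median log2 difference, printed relative to the median of all genes. A list stood apart where its median lay outside the central 95% of 10000 random lists of the same size, matched in 20 bins of mean expression. This describes these arrays and is no test of the conditions. The rule was tried on 200 random lists of 15 genes per comparison with their own differences: 4.0% to 8.5% stood apart unchanged. Shifted by 0.5 log2 units, 95.0% stood apart in bone marrow by genotype, 42.5% in fetal liver by genotype, 31.0% between the sources in wild type and 24.5% in null, and shifted by 1 unit 76.5% to 100% did. Another pair of lists, early B-lineage and reticulocyte genes, was drawn up after the data were seen.

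The rule for named genes left out probe, clone, accession and predicted-gene names, olfactory and vomeronasal receptors, and sex-linked genes, which were given with their list. Per pairwise comparison it took the 8 highest and 8 lowest genes measured on both arrays, the 4 brightest per direction among genes with no probe well above background on the other array, and 2 to 4 of the widest differences per list where that many passed 2-fold. It further took the 8 per direction with the widest difference the same way in both sources, the 5 per direction with the widest opposite differences, the 5 per direction with the lowest limma p, and always Ezh2 and Ezh1. In lists that did not stand apart fewer or no examples are printed, and for some lists members chosen for both directions are given in place of strict order. A further 2 genes picked by this rule are not reported here.

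Each result was recomputed with 9 alternatives listed in the fixed plan: quantile normalization, the median of detected probes, spike-in scaling (3 of 10 spike-in probes, well above background and unsaturated on all arrays), normexp background correction with an offset of 50, the authors' series table, the mean over all probes of a gene, only genes well above background on every array compared, no background filter, and a pseudocount of 19.3, the lowest scaled signal well above background on the array with the highest floor. The limma counts were also made with a variance trend. The alternatives added after seeing the data were 3: the percentile over all probes, the probe nearest the 3′ end, and removal, in 20 bins, of each array's trend on probe position in the transcript. List percentiles used 2000 random lists in the alternatives. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with R package data.table (version 1.17.8); figures were drawn with matplotlib 3.10.9.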

Results

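RNA was measured in mouse erythrocyte/megakaryocyte progenitors, the bone marrow and fetal liver cells that give rise to red cells and platelet-forming megakaryocytes. The cells came from E14.5 fetal liver or from adult bone marrow, and were labelled as wild type or as null for Ezh2, the histone methyltransferase of Polycomb repressive complex 2 (PRC2). Each of the 4 combinations of source and genotype was hybridised to 1 array, so no difference between 2 arrays has a replicate check, and differences are described by their size alone. Levels are spot intensities scaled to a common 75th percentile. Of 39418 probes per array, 39.0% were well above background for wild-type fetal liver, 46.4% for Ezh2-null fetal liver, 41.8% for wild-type bone marrow and 41.8% for Ezh2-null bone marrow. Across the 12874 probes well above background on all 4 arrays, the log2 values of the bone marrow arrays correlated at 0.982, while every other pair of arrays lay between 0.915 and 0.937.

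Ezh2 itself had 1 probe, on chromosome 6 of build mm9 from 47480307 to 47480366, starting 2558 bases into its transcript. Its level was 33.5 in wild-type fetal liver, 194 in Ezh2-null fetal liver, 35.4 in wild-type bone marrow and 70.03 in Ezh2-null bone marrow. The signal was thus 5.80-fold higher on the Ezh2-null array in fetal liver and 1.98-fold higher in bone marrow. The labels do not describe which part of the gene was deleted. A probe outside that part cannot check the genotype, and since this probe was brighter on the null arrays, genotypes are given here as labelled and each direction rests on the labels alone. Ezh1, which encodes the other methyltransferase of PRC2, was at least 12.2-fold higher on the array labelled Ezh2-null in fetal liver by its brightest probe (chromosome 11, 101052430 to 101052489). A second Ezh1 probe read 58.1 in wild-type fetal liver, 66.1 in null fetal liver, 50.5 in wild-type bone marrow and 69.1 in null bone marrow, so the Ezh1 probes disagreed on the size of this difference.

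**Figure D1:**
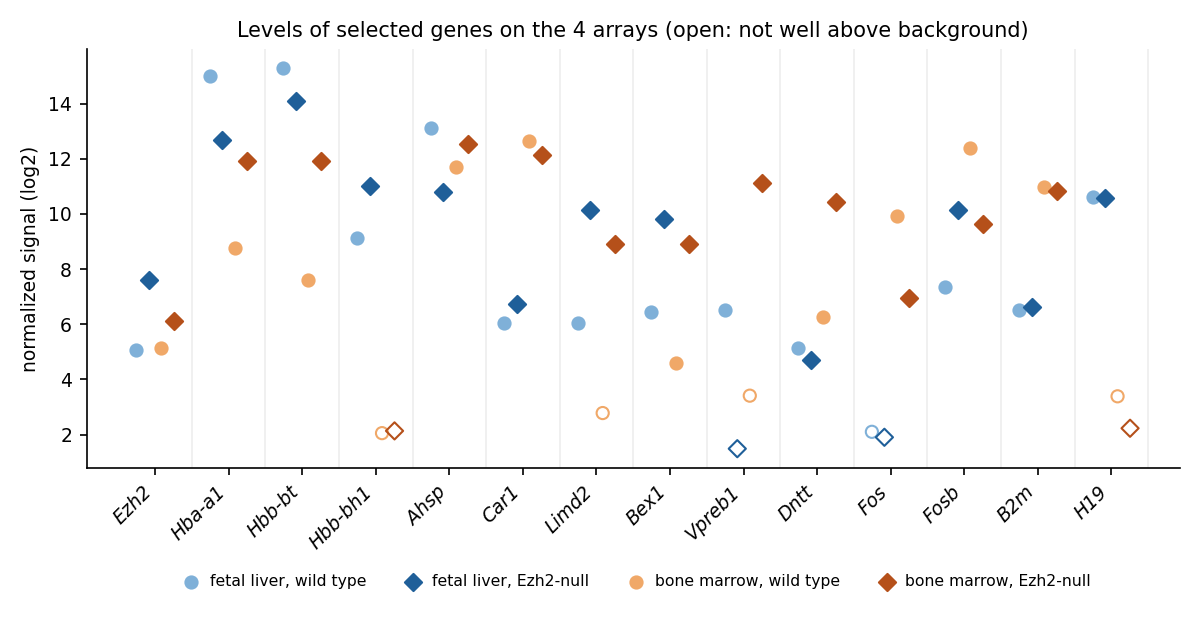
Scaled log2 signal (y axis) of 14 genes named in the text (x axis) on the 4 arrays, 1 point per array, with circles for wild type, diamonds for Ezh2-null, blue for fetal liver and orange for bone marrow. Open symbols mark signals not well above background. Ezh2 signal is highest on the Ezh2-null fetal liver array, and Hba-a1 is lower on the null array in fetal liver but higher on it in bone marrow.

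The first comparison set Ezh2-null against wild-type progenitors from fetal liver. The adult-type globins, which make up haemoglobin, were lower on the array labelled Ezh2-null: Hba-a1 by 4.99-fold, Hba-a2 by 4.17-fold, Hbb-b2 by 2.44-fold and Hbb-bt by 2.28-fold. Under 2-fold fell Hbb-b2 with spike-in scaling (−0.83 log2) and Hbb-bt with quantile normalization (−0.58), spike-in scaling (−0.73) and the trend on probe position removed (−0.96). The embryonic globins were higher, Hbb-bh1 by 3.78-fold, Hba-x by at least 4.57-fold and Hbb-y by at least 3.04-fold. Among regulators of globin switching, Myb was 4.06-fold and Bcl11a 2.99-fold higher. Of 40 erythroid genes measured, 6 were at least 2-fold higher and 15 lower. Lower were the α-globin chaperone Ahsp (5.0-fold), the haem pathway gene Urod (3.71-fold), and Mgst3 (6.02-fold). Higher were the membrane skeleton gene Epb41 (5.73-fold) and the transferrin receptor Tfrc (3.35-fold).

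Components of PRC2 and PRC1 stood above random lists in fetal liver. Of 22 measured, 7 were higher on the null array and 3 lower, and the list median lay 0.64 log2 above that of all genes, at percentile 99.35 of 10000 random lists matched on expression. This place was lost under 5 settings: the list lay at 0.18 with all probes of a gene averaged, 0.23 with detection on every array, 0.34 with normexp, 0.37 with the probe nearest the 3′ end and 0.38 with the trend on probe position removed. Higher were Ezh1, Ezh2, the PRC2 cofactor Mtf2 (at least 7.63-fold), the PRC2 core subunit Eed (6.23-fold) and the PRC1 subunit Bmi1 (at least 5.54-fold). Lower were Phc2 (3.19-fold) and Ring1 (3.01-fold). The genes encoding plasma proteins and other hepatocyte products stood below random lists, with 0 of 10 measured members higher, 5 lower and a relative median of −0.75 (percentile 0.14). With detection on every array 5 members were left at −0.38, and the list no longer stood apart. The retinol carrier Rbp4 was at least 8.04-fold lower and the apolipoprotein gene Apoa2 5.27-fold lower. Of the sex-linked genes only Xist, the RNA that coats the inactive X chromosome, was measured. It was at least 38.5-fold higher on the null array by the brighter of its 2 probes. The probe nearest the 3′ end was also detected on the null array alone (14.4). That signal lies under the wild-type floor of 19.3, so the difference was entered as 0. By that probe the sex-linked list no longer stood apart (relative median 0.12), which does not speak against the difference. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were not well above background on any of the 4 arrays. The labels do not give the sex of the animals, and the genotype differences in fetal liver are not adjusted for it.

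No other list left the central 95% of random lists in fetal liver, and the remaining 18 lay between percentiles 4.54 and 97.28. The globin and regulator list, with 5 of 10 higher and 4 lower, was the highest of these, and passed the edge with spike-in scaling and 3 other settings. With the median of detected probes and the series table its relative median was 0.69, as in the main setting. There the draw of random lists alone could place it outside. Other lists passed it too: the p53 and apoptosis list with normexp (relative median 0.46), all probes averaged (0.54) and no background filter (0.70), the developmental transcription factors with all probes averaged (−0.33) and the pseudocount (−0.26), the Hox (−0.25) and fetal-type (0.38) lists with normexp, proliferation genes with all probes averaged (0.24), the erythroid list with detection on every array (−0.30) and the megakaryocyte list with no filter (0.38). Of random lists of 15 genes shifted by 0.5 log2 units, 42.5% were found in this comparison, so list shifts of that size could be missed. Counts of higher and lower members were 8 and 3 of 32 proliferation genes, where the cycling marker Mki67 was 8.44-fold and the replication helicase subunit Mcm4 4.81-fold higher while the clamp Pcna was 2.57-fold lower. They were 3 and 1 of 17 megakaryocyte genes, with Plek at least 13.2-fold and the integrin Itgb3 6.61-fold higher, and 3 and 0 of 14 stem and multipotent progenitor genes, with the receptor Kit 3.78-fold higher. Among 10 fetal-type progenitor genes, 3 were higher and 0 lower, and these were Arid3a (at least 9.24-fold), the chromatin protein Hmga2 (at least 6.41-fold) and the let-7 inhibitor Lin28b (at least 4.62-fold). Of 15 imprinted genes 3 were higher and 0 lower, including Igf2r (5.41-fold). Of 15 immediate-early and stress genes 4 were higher and 1 lower, with Klf6 at least 16.6-fold and Ddit4 16.5-fold higher. Of 14 p53 and apoptosis genes 3 were higher and 2 lower, with Sesn2 7.32-fold higher and Bcl2l11 at least 8.64-fold lower. Higher and lower members numbered 0 and 1 of 16 developmental transcription factors, 1 and 1 of 11 Hox genes, 0 and 2 of 13 cell cycle inhibitors and 2 and 1 of 14 granulocyte and macrophage genes. They numbered 0 and 1 of 5 mast cell, basophil and eosinophil genes, 0 and 1 of 11 lymphoid genes, 0 and 1 of 6 endothelial and stromal genes, 0 and 1 of 10 interferon-stimulated genes and 4 and 1 of 15 reference genes. For scale, the reference gene Sdha was 3.69-fold higher and Hprt 2.57-fold higher.

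Outside the lists, the highest genes detected on both fetal liver arrays were X-linked Morc4 (27.6-fold), Prrc2c (21.4-fold), the RNA helicase gene Dhx9 (21.3-fold), the chloride transporter gene Clcn3 (17.8-fold), Znhit6 (17.0-fold), the vesicle sorting gene Vps33b (17.0-fold), Limd2 (17.0-fold) and the stress-induced Nupr1 (16.9-fold). The lowest were Tex19.1 (11.6-fold lower), the sorting nexin Snx15 (10.2-fold), Fignl2 (9.99-fold), Zfp74 (8.87-fold), the carboxypeptidase Cpb2 (8.66-fold), Ufsp1 (8.65-fold), Aspdh (8.60-fold) and Denr (8.28-fold), whose probe nearest the 3′ end went the other way. Detected on the null array alone, with no probe of the gene detected on the other, were Ccdc174 (at least 28.4-fold higher), the GTPase Ralb (27.6-fold), the imprinted growth-factor adaptor Grb10 (25.7-fold) and Ahcyl2 (23.8-fold), each fold a lower bound. Detected on the wild-type array alone were the histone gene H2bc18 (at least 25.9-fold lower), Mm2pr (11.9-fold), the protein kinase A subunit Prkaca (10.6-fold) and the adenylyl cyclase Adcy4 (10.4-fold), again as bounds.

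Of 16252 genes compared in fetal liver, 2504 were at least 2-fold higher on the null array and 2155 lower, 934 and 450 of them as bounds. The median of all genes was −0.14, and the null array was higher for 53.7% of the genes called, against 82.6% with spike-in scaling, under which that median was 0.23, and 41.7% with the percentile over all probes. The difference went up along the transcript: its median was −0.63 in the 762 genes with the lowest probe positions and 0.27 in the 761 with the highest, against 0.03 and −0.07 in bone marrow. Of 95 list members called, 39 fell under 2-fold with normexp, among them Hba-x, Hbb-y, Bcl11a, Mtf2, Bmi1, Phc2, Ring1, Hmga2, Lin28b, Sesn2 and Tfrc, and 16 with spike-in scaling, including Pcna (−0.90). With the trend on probe position removed, the PRC2 and PRC1 list no longer stood apart, and the erythroid list (−0.60), the developmental transcription factors (−0.62) and the megakaryocyte list (0.66) did.

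**Figure D2:**
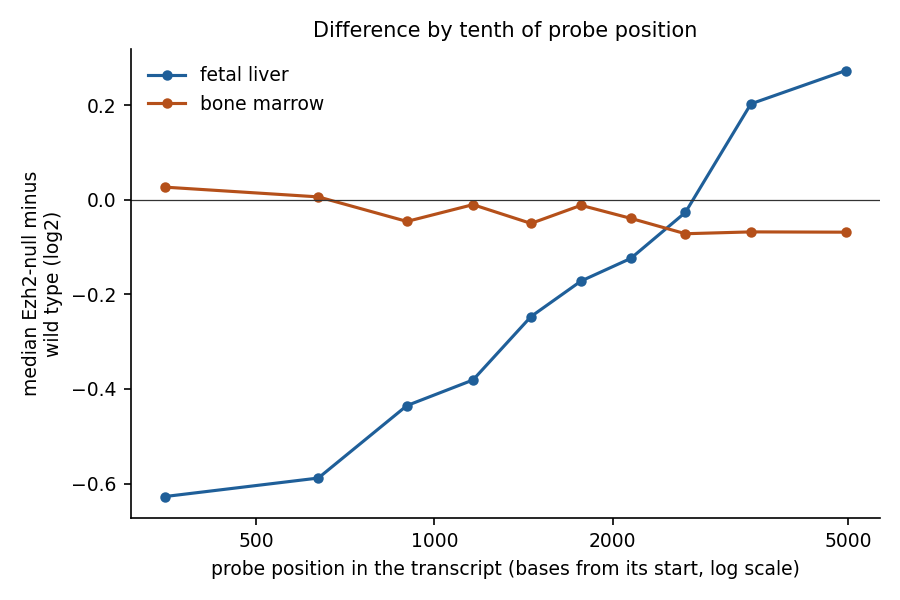
Median log2 difference between Ezh2-null and wild type (y axis) in 10 equal groups of 7617 genes ordered by probe position in the transcript (x axis, bases from its start, log scale), in fetal liver (blue) and bone marrow (orange). The fetal liver median goes from −0.63 to 0.27, and the bone marrow median from 0.03 to −0.07.

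The second comparison set Ezh2-null against wild-type progenitors from adult bone marrow. Some lymphoid genes were higher on the array labelled Ezh2-null. The surrogate light chain genes Vpreb1 and Vpreb3 were at least 198-fold and at least 13.4-fold higher, the DNA polymerase Dntt, which adds bases at antigen receptor joints, was 18.0-fold higher (76.6 to 1381), and the B-cell receptor genes Cd79b and Cd79a were at least 7.83-fold and 2.68-fold higher. Of 18 lymphoid genes measured, 10 were higher and 0 lower, with a relative median of 1.23 (percentile 100). In a list of early B-lineage genes drawn up later and sharing no gene with this one, 2 of 11 measured members were higher and 1 lower, at percentile 29.1.

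Adult globins were also higher on the null bone marrow array, opposite to fetal liver: Hbb-bt by 19.8-fold, Hba-a1 by 8.90-fold, Hbb-b2 by 8.41-fold and Hba-a2 by 6.59-fold. Myb was 3.63-fold lower, which left 4 of 7 measured members of the globin list higher and 1 lower (relative median 2.75, percentile 100). Of 39 erythroid genes 6 were higher and 1 lower, at percentile 100 with a relative median of 0.32. Klf1, the regulator of adult globin and other erythroid genes, was 3.17-fold higher, the anion exchanger Slc4a1 2.85-fold, Trim10 2.53-fold and the haem synthesis enzyme Alas2 2.43-fold, while Tfrc was 2.14-fold lower. Megakaryocyte genes stood above (5 of 15 higher, 1 lower, relative median 0.42, percentile 99.89), though no longer with all probes of a gene averaged (0.03) or with no background filter (0.05), with the platelet factor Pf4 3.18-fold, Treml1 at least 3.17-fold and Vwf 2.99-fold higher and Gp5 at least 2.85-fold lower. Proliferation genes reached percentile 100 with a relative median of 0.42, although only Aurka (2.03-fold) of 29 passed 2-fold.

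Immediate-early and stress genes stood below on the null bone marrow array. Of 18 measured, 11 were lower and 0 higher, with a relative median of −1.08 (percentile 0). The AP-1 genes Jund (9.67-fold), Fos (7.94-fold) and Fosb (6.70-fold), Ier3 (7.51-fold) and Egr1 (5.69-fold) were lower. The remaining 14 lists with measured members lay between percentiles 8.81 and 95.97; the Hox list (0.16) and cell cycle inhibitors (−0.23) left the range with normexp, and the fetal-type list (0.36) with detection on every array. Higher and lower members numbered 2 and 1 of 17 PRC2 and PRC1 components, with Cbx2 2.94-fold higher and Mtf2 at least 4.60-fold lower. They numbered 0 and 1 of 14 developmental transcription factors, 1 and 0 of 9 Hox genes (Hoxa3, at least 4.88-fold higher) and 2 and 2 of 11 cell cycle inhibitors. Of 14 stem and multipotent progenitor genes, 2 were higher and 1 lower, and the transcription factor gene Mycn was 8.25-fold higher. Counts were 1 and 1 of 14 granulocyte and macrophage genes, 1 and 1 of 5 mast cell, basophil and eosinophil genes, 2 and 0 of 5 hepatocyte genes and 0 and 0 of 5 endothelial and stromal genes. They were 1 and 0 of 5 fetal-type progenitor genes, 1 and 1 of 10 imprinted genes, 1 and 3 of 13 interferon-stimulated genes, 2 and 2 of 12 p53 and apoptosis genes and 0 and 3 of 16 reference genes. No sex-linked gene was measured in bone marrow.

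Apart from globins and Dntt, the highest genes detected on both bone marrow arrays were Fxyd6 (30.7-fold), the B-cell coactivator Pou2af1 (22.2-fold), Bex1 (19.9-fold), Eya2 (14.9-fold), the retinal reductase Dhrs3 (11.7-fold) and the surface antigen Thy1 (10.1-fold). The lowest besides Jund and Fos were the interferon-induced Bst2 (15.4-fold lower), the taurine transporter Slc6a6 (13.6-fold), Sertad2 (13.6-fold), Smim13 (9.55-fold), Taok3 (8.92-fold) and Tgs1 (8.16-fold). Detected on the null array alone, again with no probe detected on the other, were besides Vpreb1 the sulfotransferase Chst1 (at least 33.98-fold higher), Vpreb2 (16.05-fold) and Gstt1 (15.8-fold). Detected on the wild-type array alone were the NF-κB inhibitor Tnfaip3 (at least 21.9-fold lower), Hlcs (17.3-fold), Zfp994 (11.9-fold) and the Argonaute gene Ago3 (11.2-fold). Of 15275 genes compared, 694 were higher and 1167 lower, 271 and 479 of them as bounds, and the median of all genes was −0.03. The lymphoid list stayed above at 0.47 with normexp. Of 71 list members called, 40 fell under 2-fold with normexp, among them Cd79a, Slc4a1, Alas2, Treml1, Gp5, Aurka, Cbx2, Mtf2, Hoxa3 and Tfrc, which also did with quantile normalization (−0.92 log2) and the percentile over all probes (−0.99). The share of higher genes was 37.3%, and 46.2% with the percentile over all probes.

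**Figure D3:**
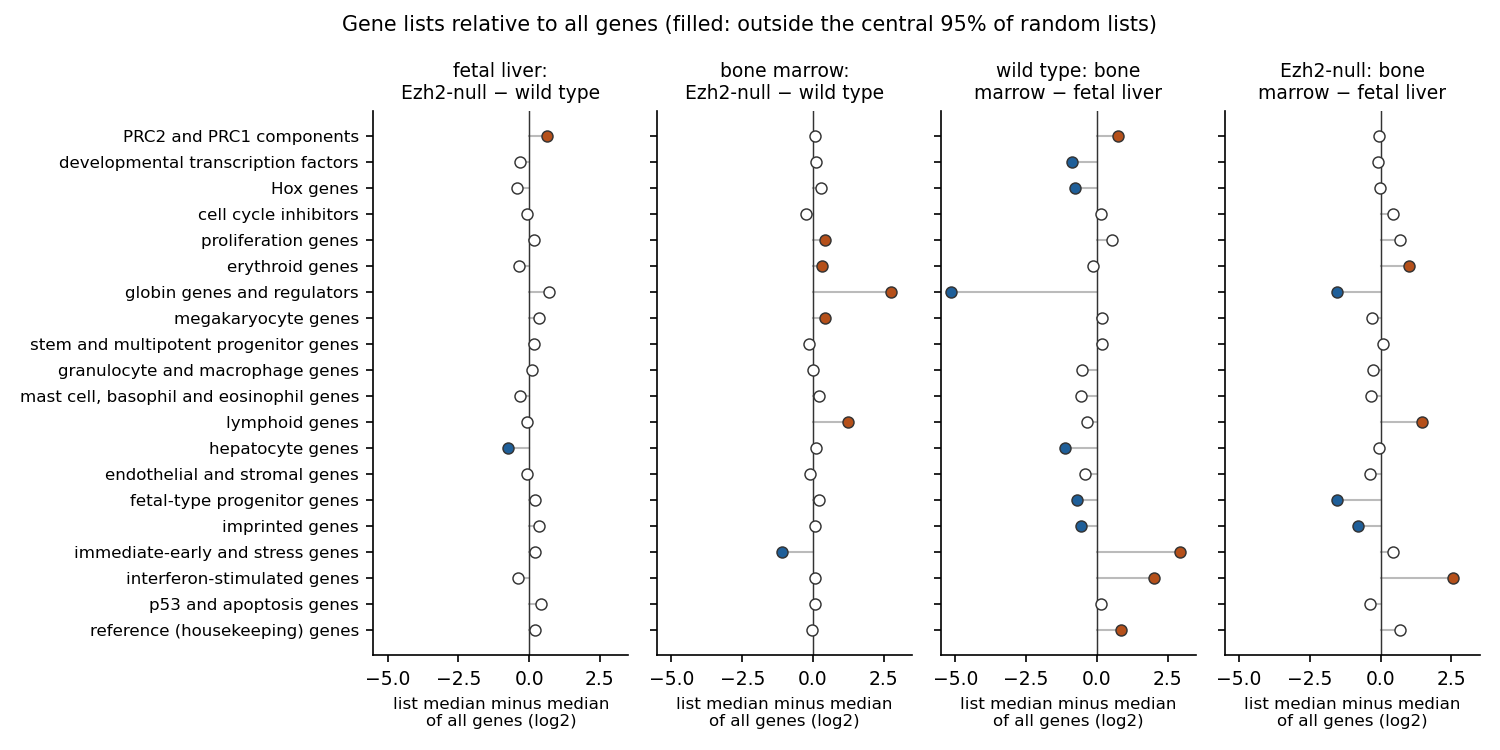
Median log2 difference of each gene list minus that of all genes (x axis) for 20 lists (y axis) in the 4 pairwise comparisons, with 1 point per list. Orange points lie above the central 95% of matched random lists, blue points below it, and open points within it. The lymphoid list lies at 1.23 in bone marrow by genotype, and the globin list at −5.14 between the sources in wild type.

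The 2 by 2 design also asks whether the genotype difference was alike in both sources. Limd2 (17.0-fold in fetal liver and at least 42.9-fold in bone marrow), the X-linked neighbours Bex1 (10.4-fold and 19.9-fold) and Bex2 (10.5-fold and at least 14.0-fold), and Chst1 (at least 8.97-fold and at least 33.98-fold) were higher on the null array in both. Also higher in both were Mical1 (6.95-fold and at least 6.10-fold), the palmitoyltransferase Zdhhc5 (5.97-fold and 8.40-fold), the aldolase Aldoc (6.29-fold and at least 5.76-fold) and Stambpl1 (at least 6.32-fold and 5.33-fold). By the probe nearest the 3′ end, Limd2 was 0.34 log2 higher in fetal liver, under 2-fold, and neither Limd2 nor Zdhhc5 went the same way in bone marrow. Lower in both were Appbp2 (4.58-fold and at least 7.76-fold), the GTPase Arl3 (at least 7.13-fold and 4.53-fold), the adaptor Crkl (4.21-fold and at least 4.63-fold), Pdcl (3.95-fold and 4.67-fold), Cdadc1 (at least 4.43-fold and 3.77-fold), the hyaluronidase Hyal2 (5.20-fold and 3.74-fold), Snx2 (at least 3.34-fold and at least 3.603-fold) and Snapc1 (at least 3.26-fold and 4.63-fold). No other probe of Pdcl was measured on both fetal liver arrays, so its fetal liver call rests on 1 probe. The difference was −0.01 with all probes averaged, which brings in signal not well above background. By the probe nearest the 3′ end it was a bound entered as 0, which does not show equal levels. With normexp, Zdhhc5 (0.72 log2) and Stambpl1 (0.78) fell under 2-fold in fetal liver, Arl3 (−0.84), Crkl (−0.93), Cdadc1 (−0.94) and Hyal2 (−0.56) in bone marrow, and Snx2 in both, and with the pseudocount so did Snx2 in both and Snapc1 in fetal liver.

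Among 13864 genes compared in both sources, 133 were at least 2-fold higher on the null array in both, where independent lists would share 83.7, and 83 were lower in both, where they would share 122.9. Genes higher in fetal liver and lower in bone marrow numbered 423 (139.7 for independent lists), and those lower in fetal liver and higher in bone marrow 93 (73.6). With spike-in scaling the 4 numbers were 203, 41, 483 and 60 (139.5, 41.3, 198.4 and 29.0 for independent lists), and with the percentile over all probes 142, 85, 325 and 146 (87.4, 142.0, 99.6 and 124.7), while with no background filter 484 were lower in both against 465.1. The widest opposite differences belonged to Sertad2 (4.96-fold higher in fetal liver, 13.6-fold lower in bone marrow), the splicing regulator Ptbp3 (12.6-fold and 5.27-fold), Bend3 (15.02-fold and 3.605-fold), Jpt2 (9.50-fold and 5.19-fold) and Fosb (6.97-fold and 6.70-fold). By the probe nearest the 3′ end, the fetal liver differences of Sertad2 and Jpt2 were at least 0.45 and at least 0.01 on the log2 scale. These are bounds, since that probe was not well above background on both arrays, and they do not contradict the wider differences. With all probes averaged the bone marrow difference of Ptbp3 was −0.99. In the other direction they belonged to Hbb-bt, Hba-a1 and Hba-a2, the peroxisomal gene Pex11g (6.75-fold lower, 4.89-fold higher) and the Notch modifier Lfng (7.90-fold lower, 3.52-fold higher). The difference of the differences was at least 4-fold for 1050 of 11171 genes detected on all arrays, with the fetal liver difference above the bone marrow one for 711 of them and below it for 339. That split was 534 and 528 with the percentile over all probes, and 1046 and 161 with spike-in scaling. Across genes, which are not independent replicates, the differences in the 2 sources correlated at r = −0.23 (Spearman rho −0.22).

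**Figure D4:**
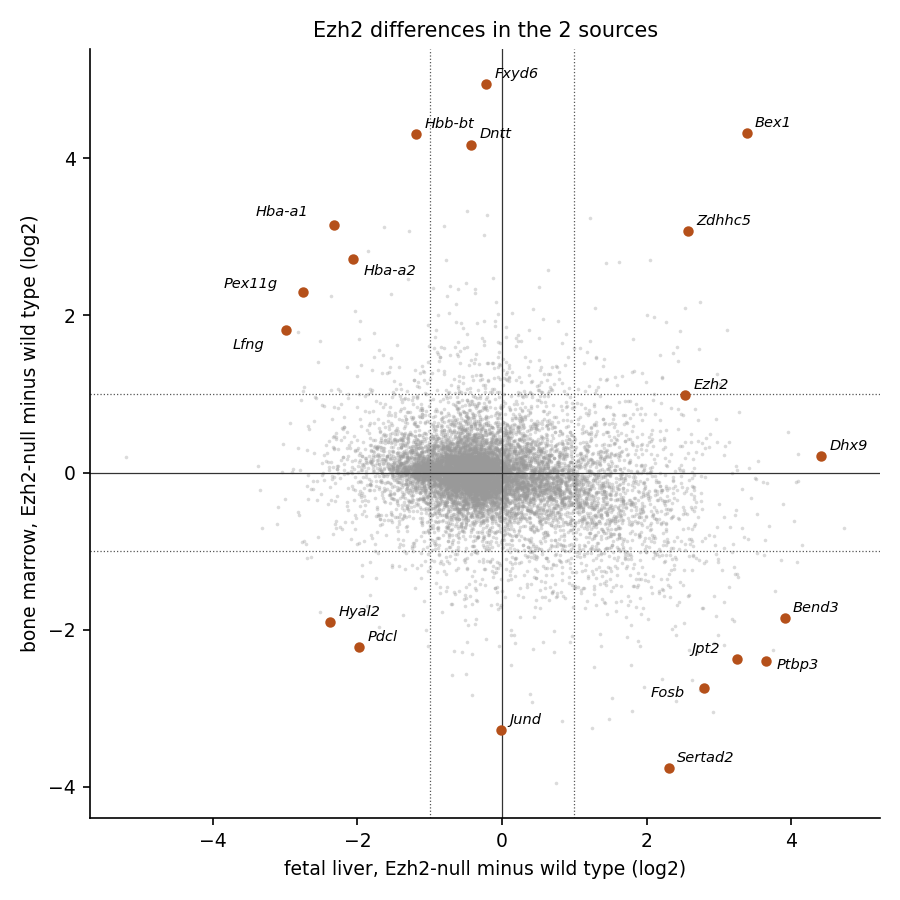
Log2 difference between Ezh2-null and wild type in fetal liver (x axis) and bone marrow (y axis), 1 grey point per gene for 11171 genes detected on all 4 arrays, with named genes in orange. Dotted lines mark 2-fold differences. Bex1 and Zdhhc5 lie above both upper lines, and Hba-a1, Hba-a2 and Hbb-bt lie lower in fetal liver and higher in bone marrow.

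An additive limma fit over the 4 arrays, with source and genotype as terms, set each effect against its disagreement between the other pair of groups, with 1 residual degree of freedom. Signals under the highest array floor, 19.3, were raised to it before the fit. Differences and SEs of genes dim on some array therefore rest on that floor. Among those named below are Limd2, Chst1 and Bex2, with wild-type bone marrow signals of 6.86, 11.8 and 2.47. No gene of 16249 passed an adjusted p of 0.05 for genotype, and the smallest Benjamini-Hochberg adjusted p was 0.996. An unadjusted limma p below 0.05 was reached by 278 genes. That is a smaller share than the 0.05 that would reach it with no genotype effect. The 5 lowest limma p-values with higher signal on the null arrays belonged to Limd2 (log2 difference 4.36, SE 0.42), Bex1 (3.85, SE 0.45), Chst1 (3.77, SE 0.49), Bex2 (3.20, SE 0.41) and Zdhhc5 (2.72, SE 0.41). Those with lower signal were Appbp2 (−2.10, SE 0.41), Pdcl (−2.10, SE 0.41), Arl3 (−2.02, SE 0.42), Tspyl3 (−1.84, SE 0.41) and the chromatin remodeller Arid1a (−2.22, SE 0.50). For source 0 genes passed as well, with 2662 at an unadjusted limma p below 0.05 and a smallest adjusted p of 0.110. The lowest source p-values were those of Sdsl (5.24, SE 0.41), Car1 (6.00, SE 0.48), Zfp36 (5.27, SE 0.43), Psmb9 (5.60, SE 0.50) and Gsn (4.31, SE 0.40), higher in bone marrow, and of H19 (−6.32, SE 0.40), Lgals1 (−5.36, SE 0.44), Ndufa4l2 (−4.94, SE 0.41), Lhx2 (−4.89, SE 0.42) and Pkm (−7.01, SE 0.61). In simulated data the fit recovered 72.8% of genes changed by 4 log2 units and 0.8% of those changed by 2. The simulation changed 50 genes at each size and held no source difference, unlike the real arrays. On those, Limd2 did not pass at 4.36, so effects of that size and smaller could be missed at this array number. Counts for source differed with the setting: quantile normalization gave 212 genes and the percentile over all probes 959, and the latter gave 8 for genotype. With that percentile the fit took a common variance for all genes as known, so its counts do not rest on the spread of each gene.

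The third comparison set adult bone marrow against fetal liver in wild-type progenitors. Globins were far lower in bone marrow: Hbb-bt by 203-fold (39859 to 196), Hbb-b2 by 78.6-fold, Hba-a1 by 75.8-fold, Hba-a2 by 55.7-fold and embryonic Hbb-bh1 by at least 49.7-fold, for 6 of 8 lower and 0 higher (relative median −5.14, percentile 0), a place lost with no background filter (−0.13). Immediate-early genes were higher in bone marrow. Of 18 measured, 12 were higher and 0 lower (relative median 2.95, percentile 100), with Fos at least 50.9-fold, the mRNA decay factor Zfp36 48.4-fold, Fosb 33.1-fold, Egr1 at least 31.4-fold and the phosphatase Dusp1 20.6-fold higher. Interferon-stimulated genes were higher as well, in 8 of 13 with 2 lower (relative median 2.01, percentile 100), including Ifi27 (8.07-fold) and Bst2 (6.45-fold).

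Fetal-type and imprinted genes stood below random lists in wild-type bone marrow under the main setting. Among imprinted genes 2 of 14 were higher and 8 lower (relative median −0.55, percentile 1.65), with H19 at least 142-fold, Snrpn at least 15.3-fold and Dlk1 at least 12.4-fold lower. Among fetal-type progenitor genes 1 of 8 was higher and 5 lower (−0.71, percentile 2.14), with the RNA-binding protein gene Igf2bp1 at least 23.9-fold and Tfdp2 6.78-fold lower. Hepatocyte genes (0 of 8 higher, 6 lower, −1.11, percentile 0.10) were led by Apoa2, 11.9-fold lower. Developmental transcription factors, textbook targets of PRC2 in embryonic stem cells, had 0 of 13 higher and 10 lower (−0.87, percentile 0.09), among them Lhx2 at least 61.8-fold lower. Hox genes had 0 of 9 higher and 8 lower (−0.76, percentile 1.11), with Hoxa6 4.09-fold lower. PRC2 and PRC1 components (6 higher and 6 lower of 21, 0.76, percentile 99.34) and reference genes (7 and 4 of 16, 0.86, percentile 99.46) stood above. Cbx6 was 4.03-fold higher. Ezh1 was at least 6.39-fold higher by its brightest probe, but its second probe read 58.1 in fetal liver and 50.5 in bone marrow, and the difference fell under 2-fold with all probes averaged (0.67 log2) and with normexp (0.62). B2m, the light chain of class I antigen-presenting molecules, was 21.5-fold higher. Each list of this paragraph lost its place under some setting: the fetal-type list with quantile normalization (relative median −0.52), normexp (−0.42), the pseudocount (−0.22) and all probes averaged (−0.19), and the imprinted list with the trend on probe position removed (−0.58), all probes averaged (−0.43), quantile normalization (−0.41), the pseudocount (−0.20), detection on every array (−0.06) and no background filter (−0.01). The developmental transcription factors lost their place with all probes averaged (−0.54), detection on every array (−0.53) and no filter (−0.05), the Hox list (−0.05) with no filter, the hepatocyte list with detection on every array (−0.38), the PRC2 and PRC1 list with normexp (0.38) and the reference genes with all probes averaged (0.63).

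The remaining 10 lists lay between percentiles 3.01 and 85.1; with all probes averaged the granulocyte and macrophage list (−0.60) and the p53 and apoptosis list (0.94) left the range, as did the endothelial and stromal list with the pseudocount (−0.49) and the erythroid list with the trend on probe position removed (−0.196). Erythroid genes had 5 of 39 higher and 14 lower, with the carbonic anhydrase genes Car1 96.1-fold and Car2 6.94-fold higher and Slc4a1 11.7-fold lower. Higher and lower members numbered 5 and 4 of 29 proliferation genes, 3 and 4 of 13 cell cycle inhibitors, 1 and 4 of 13 megakaryocyte genes and 3 and 3 of 14 stem and multipotent progenitor genes, where Gata2 was at least 13.6-fold higher. They numbered 0 and 7 of 12 granulocyte and macrophage genes, 0 and 4 of 5 mast cell, basophil and eosinophil genes, 1 and 5 of 10 lymphoid genes, 0 and 3 of 5 endothelial and stromal genes and 1 and 3 of 12 p53 and apoptosis genes. Among other named genes, Psmb9, an immunoproteasome subunit, was at least 76.7-fold higher, Paqr9 at least 44.96-fold (0.31 log2, under 2-fold, with all probes averaged), Sdsl 34.8-fold, the histone gene H2bc4 26.5-fold and Gramd4 25.0-fold. Lower in bone marrow were the glycolytic enzyme gene Pkm (at least 453-fold), the lactate transporter Slc16a3 (137-fold), Mrap (55.2-fold), the galectin Lgals1 (53.3-fold), Zdhhc22 (at least 53.2-fold) and the histone methyltransferase Kmt2a (38.0-fold).

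Of 15379 genes compared between wild-type arrays, 2016 were at least 2-fold higher in bone marrow and 4896 lower, with the median of all genes at −0.58, so that the list values above are given relative to it. The split depended on the scaling, with 29.2% of the called genes higher, against 51.9% with quantile normalization, 54.9% with the percentile over all probes and 94.7% with spike-in scaling, under which the median of all genes was 0.71. Of 158 list members called, 79 fell under 2-fold with spike-in scaling, including Hoxa6 (−0.71 log2), 45 with quantile normalization, 42 with the percentile over all probes and 27 with normexp.

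The fourth comparison made the same contrast in Ezh2-null progenitors. Lymphoid genes were higher in bone marrow here, in 8 of 18 with 1 lower (relative median 1.46, percentile 100). Vpreb1 was at least 170-fold, Dntt 53.1-fold and Vpreb3 at least 11.5-fold higher, and the coreceptor Cd4 was 3.21-fold lower. Interferon-stimulated genes were again higher, in 7 of 12 with 1 lower (2.56, percentile 100), with the transcription factor Irf9 21.2-fold and Ifi27 20.4-fold higher but Bst2 4.03-fold lower. Globins were lower in bone marrow: Hbb-bt by 4.51-fold, Hbb-b2 by 3.84-fold and Hba-a2 by 2.03-fold, a call lost with 5 other scalings (−0.12 log2 with spike-ins), while embryonic Hbb-bh1 was at least 209-fold and Hba-x at least 8.83-fold lower. The globin list had 0 of 10 higher and 7 lower (−1.55, percentile 0). With detection on every array, which leaves out genes given as bounds, 10 lymphoid and 7 globin members were left. Those lists, at 0.45 and −0.62, no longer stood apart, and with no background filter the interferon-stimulated list (0.07) did not.

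Fetal-type progenitor genes had 1 of 9 higher and 7 lower in null bone marrow (relative median −1.55, percentile 0.06), with Arid3a at least 17.9-fold, Igf2bp1 at least 15.1-fold, Hmga2 at least 12.4-fold and Lin28b at least 8.93-fold lower. Imprinted genes had 1 of 14 higher and 9 lower (−0.82, percentile 0.34), with H19 at least 151-fold, Dlk1 25.3-fold and Grb10 11.6-fold lower. Detection on every array leaves out all genes given as bounds, and 4 fetal-type and 10 imprinted members were left. Neither list then stood apart, the fetal-type list turning to 0.09 and the imprinted list lying at −0.41. Since Arid3a, Igf2bp1, Hmga2 and Lin28b drop out by that rule, this does not speak against their differences. Erythroid genes stood above (11 of 40 higher, 7 lower, 1.01, percentile 99.88), with Car1 42.3-fold and the water channel Aqp1 7.26-fold higher and Epb41 13.7-fold lower. Xist was at least 74.4-fold lower by the brighter of its 2 probes. The sex-linked list no longer stood apart by the probe nearest the 3′ end (−0.02) or with no background filter (−0.01). That probe was detected in null fetal liver (14.4) and not in bone marrow, so it gives only a bound, limited by the floor. The remaining 14 lists lay between percentiles 4.17 and 86.3, and of them the p53 and apoptosis list left the range with normexp (−0.24) and the pseudocount (−0.36). Higher and lower members numbered 6 and 11 of 24 PRC2 and PRC1 components, with Mtf2 at least 14.7-fold and Bmi1 at least 10.71-fold lower. They numbered 0 and 2 of 17 developmental transcription factors, with Lhx2 36.1-fold lower, 0 and 1 of 10 Hox genes, 2 and 4 of 11 cell cycle inhibitors, with Cdkn2c 26.7-fold higher, and 5 and 8 of 32 proliferation genes, with the kinesin Cenpe 27.2-fold lower. They numbered 2 and 8 of 18 megakaryocyte genes, 4 and 4 of 14 stem and multipotent progenitor genes, 0 and 7 of 16 granulocyte and macrophage genes, 1 and 1 of 6 mast cell, basophil and eosinophil genes and 0 and 3 of 8 hepatocyte genes. Counts were 0 and 3 of 6 endothelial and stromal genes, 7 and 4 of 18 immediate-early and stress genes, 1 and 6 of 14 p53 and apoptosis genes and 4 and 4 of 16 reference genes.

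Further genes higher in null bone marrow than in null fetal liver were Zfp36 (at least 46.0-fold), Galnt10 (44.0-fold), Sdsl (41.2-fold), Btnl10 (39.5-fold), the interferon-induced exonuclease Isg20 (37.9-fold), Psmb9 (30.7-fold), Pou2af1 (at least 29.2-fold), the protease Ctse (at least 29.1-fold) and C1qtnf12 (27.4-fold). Lower were the stress-induced pseudokinase Trib3 (at least 451-fold), the glucose transporter Slc2a1 (101-fold), the adenylate kinase Ak4 (at least 92.7-fold), Rprd1a (at least 90.8-fold), Tent4b (72.5-fold), Sertad2 (67.2-fold), Pkm (63.5-fold), the RNA-binding protein gene Larp1 (50.8-fold), Ndufa4l2 (54.1-fold) and Ppip5k2 (47.3-fold). Of 16684 genes compared, 1731 were higher and 4482 lower, and the median of all genes was −0.51. The share higher was 27.9%, against 42.3% with the median of detected probes, 52.2% with quantile normalization, 64.2% with the percentile over all probes and 75.2% with spike-in scaling, which moved the median to 0.37. Of 156 list members called, 64 fell under 2-fold with normexp, including Bst2 (−0.91 log2), 51 with spike-in scaling, including Cd4 (−0.78), 42 with the percentile over all probes, 37 with quantile normalization and 29 with the median of detected probes.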

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

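In this part, removal of the trend on probe position, the bone marrow trend, both tests of scaling and the intervals over list members were chosen only after the results they bear on were seen. The paired-probe, B-lineage and reticulocyte tests were set out before their own outcomes were known, but after the patterns they address had been seen.

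For 10 genes the Ezh2-null array lay above wild type in one source and below it in the other. The difference of the differences, fetal liver minus bone marrow on the log2 scale, was 6.07 for Sertad2, 6.05 for Ptbp3, 5.76 for Bend3, 5.62 for Jpt2 and 5.55 for Fosb. It was −5.496 for Hbb-bt, −5.47 for Hba-a1, −5.04 for Pex11g, −4.80 for Lfng and −4.78 for Hba-a2. With 1 array per group these differences between sources were not tested. They are the widest 5 per direction among the 232 genes open to naming that were at least 2-fold apart in opposite directions and detected on all 4 arrays. For Ptbp3 another probe went the other way in bone marrow. The fetal liver difference of Hbb-bt fell under 2-fold with quantile normalization, spike-in scaling and the trend removed.

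Adult globins were lower on the null fetal liver array and higher on the null bone marrow array. The 7 scalings tried do not account for this: over them the median of Hba-a1, Hba-a2, Hbb-b2 and Hbb-bt was at most −1.21 in fetal liver and at least 2.79 in bone marrow. Those that change 1 factor per array differed little, from 0.28 to 0.90 log2 in fetal liver and from −0.20 to −0.09 in bone marrow. They could not have turned either sign, so other scalings are not covered. Different shares of late red cells in the samples may contribute and cannot be told apart from a difference within progenitors. Reticulocyte genes outside the fixed lists lay at percentile 68.2 in bone marrow and 14.2 in fetal liver, neither far enough out to decide, with intervals over members of −0.12 to 0.35 and −0.85 to 0.13 that span the middle of random lists. A genotype effect on globin genes that differs by source, which the design could hold, stays open and untested.

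Lymphoid genes were higher on the null bone marrow array. The 7 scalings tried do not account for this: over them the list median itself was at least 0.468 and the lower end of its interval over members at least 0.168, while the median of all genes moved only between −0.03 and 0.07. Those that change 1 factor per array differed only from −0.20 to −0.09 log2 in bone marrow, too little to turn its sign. Early B-lineage cells in that sample may be the source and were tested with 19 genes outside the lymphoid list, which the progenitors may express too, as 11 were measured. Their median lay at percentile 29.1, below the bound of 50 set beforehand against this source, but its interval over members, −0.43 to 0.17, spans the middle of random lists (−0.05). Myl4 (2.71 log2) and Cnn3 (1.75) were higher while Blk, Lef1 and Ighm were not detected, so carry-over of such cells, which the labels' protocols do not rule out, and expression in null progenitors cannot be told apart.

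Genes at least 2-fold apart by genotype numbered 4659 in fetal liver and 1861 in bone marrow, and the fetal liver difference went up with probe position in the transcript. Shorter RNA from the wild-type fetal liver sample is argued against: over 558 transcripts with probes at least 500 bases apart, the upstream minus downstream difference had a median of −0.16 (interval −0.27 to −0.03), opposite to what shorter wild-type RNA would give, and loss of upstream sequence from the null sample, a sign noticed only afterwards, was not set out beforehand. The trend in medians is argued against as the whole cause, as 4685 genes were apart with it removed, against 1904 in bone marrow. That removal leaves the spread between genes as it was, so it cannot show what a poorer sample would add. The wild-type fetal liver array was the dimmest, with a 75th percentile of 337 over detected probes against 561 on the null array, and had the widest spread between spots (log2 SD 0.152). A genotype effect on long transcripts shared by both sources is argued against by a bone marrow change of −0.10 between the lowest and highest positions, against 0.90 in fetal liver. A source-specific genotype effect, the sex of the animals, sample handling and differing amplification may each contribute and stay open, since each sample was measured once.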

How the results depend on the processing

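The percentile over all probes, the probe nearest the 3′ end and the removal of the position trend were chosen after seeing the data. Of the values for whole comparisons under the alternatives, 100 kept their threshold side, stayed within 1.5 times for counts, or within an interval over genes for correlations. Another 30 moved and 4 passed 2-fold. Counts were judged by the total of both directions, which does not catch a turned split. Between sources in wild type, spike-in scaling gave 6441 calls against 6912. Of these 6102 were higher and 339 lower, against 2016 and 4896. Of list values 921 kept their place, while 33 came inside and 26 went outside the central range of random lists. Scaling by the detected median, spike-ins or the percentile over all probes changes 1 factor per array. That hardly moves a list relative to all genes, and the series table holds the same data rounded, so list values kept under these settings say little. Of named-gene values 1724 kept direction and threshold side, while 29 fell under 2-fold and 5 passed it. Where no cause is given below, the cause was not tested.

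Normexp adds an offset that compresses low signals. It gave 1849 genes 2-fold apart by genotype in fetal liver, 362 in bone marrow, 2974 between sources in null, 21 shared by both sources, 328 for the difference of differences and a correlation of −0.27. The pseudocount, which compresses likewise, gave 766 in bone marrow by genotype, 3773 between sources in wild type, 3813 in null, 70 shared and −0.26. With no background filter more genes entered, and counts were 8512 in fetal liver and 4970 in bone marrow by genotype, 12986 between sources in wild type and 11157 in null, 806 shared, 4172 for the difference of differences, with a correlation of −0.095. Asking for detection on every array compared left 1111 in bone marrow and 79 shared, with fewer genes compared. It leaves out every gene given as a bound, so a list can lose its place there by losing its widest members.

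The limma genotype count of 0 became 14 with normexp, 140 with no filter and 8 with the percentile over all probes. In these settings the fit took a common variance for all genes as known, for source as well. Their counts rest on that and not on the spread of each gene. The source count of 0 became 212 with quantile normalization, 218 with the median of detected probes, 1287 with normexp, 138 with detection on every array, 1398 with no filter, 959 with the percentile over all probes and 115 with a variance trend. The Ezh2 difference in bone marrow passed 2-fold with the median of detected probes (1.04 log2), spike-ins (1.03), the percentile over all probes (1.09) and the trend removed (1.07).

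Reversed was the fetal-type list between sources in null with detection on every array (relative median 0.090), where only 4 members were left and all bounds dropped out. Also reversed was the sex-linked list in fetal liver with no filter (−0.11), which brings in undetected Y-linked genes. Denr was reversed in fetal liver with all probes averaged (0.91) and with the 3′ probe (at least 2.67), and Limd2 (−0.13) and Zdhhc5 (−0.11) in bone marrow with the 3′ probe. The slide as a block was not run, since there was 1 slide, and leaving out an array would leave 0 residual degrees of freedom. The labels hold no replicate numbers to pair by, and the additive limma fit already compares genotypes within each source. Signal over background limits low genes: 38.97% to 46.4% of probes were well above it.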

Other observations

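The genes of this part were picked after their values were seen, and no test of them as groups was run.

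Some single genes with roles in glucose use or antigen presentation differed between the sources in both genotypes. The glucose transporter Slc2a1 was at least 37.4-fold lower in wild-type bone marrow than in fetal liver and 101-fold lower in null, the first enzyme of glucose breakdown, Hk2, 4.60-fold and 30.5-fold, the enolase Eno1 4.95-fold and 6.06-fold, and the mitochondrial protein gene Ndufa4l2, induced by low oxygen, 35.05-fold and 54.1-fold. With Pkm and Slc16a3 these stayed lower in bone marrow over the 7 scalings, with highest log2 differences of −0.88 (Hk2, wild type) and −1.69 (Eno1, null). In wild type Hk2 and Eno1 (−0.99) thus fell under 2-fold over the scalings. The class I antigen genes H2-K1 (11.1-fold and 13.98-fold) and H2-D1 (10.8-fold and 8.77-fold), B2m (21.5-fold and 18.5-fold) and the immunoproteasome subunits Psmb8 (12.4-fold and 13.4-fold) and Psmb9 were higher in bone marrow in both genotypes. Their lowest log2 differences over the scalings were 2.02 and 2.14, both for Psmb8. Probes for H2-K1 and H2-D1 can share signal with related class I genes.

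On the null fetal liver array some single genes that cells can switch on under stress were at least 2-fold higher than in wild type, while the fixed immediate-early and stress list did not stand apart (percentile 83.2). Trib3 was 11.96-fold, Ddit4 16.5-fold, Sesn2 7.32-fold, the folate enzyme Mthfd2 2.31-fold, and the serine synthesis enzyme Psat1 2.20-fold higher, and Chac1 at least 3.09-fold, while the asparagine synthetase Asns, at 1.93-fold, was not called. Over the 7 scalings Sesn2 fell to 0.99 log2, Psat1 to 0.97, Mthfd2 to 0.53 and Chac1 to 0.14, all under 2-fold, while Trib3 and Ddit4 stayed at 3.35 and 3.70 or more. Ddit3, which belongs to the same response, was 1.14-fold lower, and turned to 0.26 log2 higher under 1 scaling. In bone marrow Sesn2 was at least 7.27-fold, Psat1 2.08-fold, Ddit3 1.73-fold and Ddit4 1.53-fold lower on the null array, and Mthfd2 1.68-fold and Asns 1.39-fold higher, and Psat1 fell under 2-fold (−0.91 log2) over the scalings.

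Xist was detected on the null fetal liver array alone, by 2 probes with signals of 743 and 14.4, while its signals on the other 3 arrays were not well above background. The myeloid integrin gene Itgam had a signal of 104975 in wild-type fetal liver, 85224 in null fetal liver, 54129 in wild-type bone marrow and 53551 in null bone marrow, while the myeloid genes Lyz2 and Elane were not well above background on any array.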
